A study of Homo sapiens with 6 samples.

How the data were processed

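Gene expression was measured in 6 RNA samples of cultured human penile cells, each hybridised to 1 Affymetrix whole-transcript gene array. Per the labels, tissue was removed surgically and its cells were grown in DMEM with 10% fetal bovine serum. The cells came from 3 sources: the tunica albuginea (TA), the fibrous sheath around the erectile bodies; tissue of Peyronie disease (PD), a fibrosis of that sheath; and the corpora cavernosa (CC), the erectile bodies themselves. Cells of each source were kept for 7 days without or with transforming growth factor beta (TGF-β) at 5 ng/ml, which gave 1 array per source and treatment. The labels do not say how many donors or cultures stand behind a source, so donor, culture and source could not be separated.

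RNA was extracted with Trizol and cleaned on a column, per the labels' protocols, and a core facility ran the arrays. The deposited table holds 33297 transcript clusters and 1 value per cluster and array. The authors normalised with RMA, per the submitters' processing notes; the version was not given in the sources used here. The deposited values are intensities on a linear scale, read as such from their range of 2.76 to 24734 and their right-skewed distribution, whereas RMA usually returns log2 values. Every intensity was above 0, so log2 was taken with no pseudocount. The 6 arrays did not share 1 distribution: the median intensity was 111 and 112 on the TA arrays (untreated and TGF-β), 107 and 108 on the PD arrays, and 99.1 and 94.3 on the CC arrays. The 10th percentile of log2 intensity was 3.60 and 3.66 on the CC arrays, against 3.91 to 3.98 on the other arrays. Whether all arrays were normalised together is not given in the sources used here, and no detection p or scan batch was given either. For arrays, their number limits the precision of every value.

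Clusters were named through the platform annotation paired with the table. Of the clusters, 19460 had 1 gene symbol, 1754 had several and 12083 had none. Symbols were updated by Entrez ID to the RefSeq gene table of assembly GRCh38.p14, where 19429 of the single-symbol clusters matched; that table was used for names only and no coordinates are given, since the build of the array annotation was not stated. Each of the 18417 genes was represented by its cluster with the highest mean log2 intensity (769 genes had more than 1 cluster), and the upper 60% by mean log2 intensity, 11050 genes with a mean of at least 6.77, were tested. Clusters with several or no symbols were fitted separately.

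The main comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with TGF-β as the effect and the cell source as a block. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The fit had 2 residual degrees of freedom and 4.50 prior degrees of freedom. The 3 arrays of a treatment are 3 different sources, so the test asks whether a change was shared by the sources, and its error is the spread of the responses between them. The pairing comes from the source named in the labels. Across genes, deviations from the treatment means correlated at 0.714 for TA, 0.668 for PD and 0.757 for CC between the arrays of 1 source. Values between arrays of different sources, −0.567 to 0.0281, are held down by the centring on 3 arrays and add no separate evidence. Errors after ± are SDs of the log2 change over the 3 sources (n = 3).

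Before the data were examined, 27 gene lists were fixed: 19 pathway lists and 8 lists of cell type markers. The 22 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over these lists. Calls were repeated with an estimated correlation and with fry. With an estimated correlation camera tests on the 2 residual degrees of freedom of the fit, so few lists could pass even at a low correlation. Some lists called at the preset also had a higher estimated correlation, which raises p as well. It was 0.49 for the amino acid and stress list, 0.31 for the myofibroblast list and 0.17 for the collagens. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

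A response within 1 source, and a difference between sources, rest on single arrays and were not tested. They are given as log2 differences, as counts of genes at least 2-fold different, and as list medians with their percentile among 10000 random lists of the same size matched on mean expression. A difference between sources was counted where it was at least 2-fold in the same direction without and with TGF-β. A gene was called apart in a source where it was at least 2-fold above, or below, both other sources in both states. Correlations of responses are across genes, which are not independent replicates.

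Genes were named mainly by rules fixed before the data were examined. These were the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold and moving the same way in all sources; up to 4 members per list by absolute change; 4 genes each way per source by the gap between its response and the mean of the other sources; 8 each way per source difference by the smaller of both log2 differences; and 6 each way per source apart by the smallest of 4. Some other list members, such as SKIL, SMAD7, COL14A1 and TGFB2, lie outside these rules and were named with the data in view. Clusters without exactly 1 symbol, uncharacterised loci, small RNA, olfactory receptor and long intergenic RNA symbols, XIST and Y-linked genes were not named. Genes whose level depends on a common inherited deletion or variant, HLA genes and mitochondrial genes were left unnamed as well, a choice made after seeing the data because these are donors' cells.

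Alternatives were another or no filter on dim clusters, the mean over all clusters of a gene, quantile normalisation, median centring, no block, a trended and robust prior, each source left out, a plain paired statistic, an added fold threshold, other fold thresholds and single states. The fit was tested on simulated data of 11050 genes, 200 of them changed, in 20 runs. Each gene's spread was drawn from the fitted prior, errors were independent, and a change was the same in all sources. In that setting the fit recovered 20.5% of genes changed 1.5-fold, 85% of those changed 2-fold and 99.0% of those changed 4-fold, and 5.59% of its calls were false. These rates do not cover changes that differ between sources, as that of POSTN did (SD 1.63). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.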

Results

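The transcripts of cultured human penile cells were measured on 6 arrays, 1 for each of 3 cell sources (TA, PD and CC) without and with TGF-β at 5 ng/ml for 7 days. TGF-β induces plaque resembling Peyronie disease in animal models, according to the series' design text, and the design asks how cells of the diseased tissue, of the normal sheath and of the erectile bodies respond to it. Across the 11050 genes tested, arrays of the same source correlated at r = 0.957 (TA), 0.952 (PD) and 0.943 (CC) between treatments. The TA and PD arrays correlated at 0.962 without and 0.961 with TGF-β, and at 0.925 and 0.935 between states. The CC arrays correlated with those of the other sources at 0.902 to 0.928 in the same state and at 0.881 to 0.894 between states. Of the markers listed, 7 of 10 for fibroblasts and 9 of 12 for smooth muscle and pericytes passed the filter on dim genes, against 1 of 11 for endothelium and 2 of 12 for leukocytes. Log2 intensities lay between 10.92 and 12.48 for decorin DCN and between 11.34 and 12.23 for THY1. Those of PECAM1 and CDH5, genes of endothelial junctions, lay between 5.23 and 5.48 and between 5.87 and 6.44, and PTPRC, the pan-leukocyte antigen CD45, lay between 3.68 and 4.37, all under the filter floor of 6.77. The smooth muscle myosin gene MYH11 lay between 6.07 and 6.30.

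TGF-β raised 436 genes and lowered 364 across the 3 sources (limma with the source as a block, adjusted p under 0.05). The largest rises included the growth factor IGF1 (log2 change 3.30 ± 0.92, adjusted p = 0.00337), the matricellular protein gene POSTN (3.25 ± 1.63, adjusted p = 0.0190), the potassium channel gene KCNH1 (3.14 ± 0.64, adjusted p = 0.00157), DACT1 (3.12 ± 0.38, adjusted p = 0.00149), and NOX4, an NADPH oxidase that makes hydrogen peroxide (3.07 ± 0.56, adjusted p = 0.00149). TSPAN2 rose by 2.93 ± 0.58, PLXDC2 by 2.74 ± 0.92, AMIGO2 by 2.74 ± 0.62, PMEPA1, a feedback inhibitor of TGF-β signalling, by 2.59 ± 0.67, GPAM, an enzyme of glycerolipid synthesis, by 2.54 ± 0.30, CRISPLD2 by 2.52 ± 0.23, and the cytokine IL11 by 2.49 ± 1.05. The largest falls were those of the soluble pattern recognition gene PTX3 (−3.80 ± 0.95, adjusted p = 0.00224), the relaxin receptor RXFP1 (−3.48 ± 0.67, adjusted p = 0.00149), the hyaluronan-degrading factor CEMIP (−3.16 ± 1.07, adjusted p = 0.00535), hepatocyte growth factor HGF (−3.16 ± 0.58, adjusted p = 0.00149), and the chemokine scavenger ACKR4 (−2.92 ± 1.39, adjusted p = 0.0165). PLAT, tissue plasminogen activator, also fell (−2.91 ± 0.81), as did CLDN11 (−2.85 ± 0.57), SECTM1 (−2.52 ± 0.22), SLC7A14 (−2.44 ± 0.30), prostacyclin synthase PTGIS (−2.41 ± 0.50), the potassium channel gene KCNJ2 (−2.22 ± 1.18) and PDE5A, the cGMP phosphodiesterase blocked by sildenafil (−2.14 ± 0.79). In at least 1 source 12 of these 24 genes had an array under the filter floor of 6.77, and KCNH1, RXFP1 and SLC7A14 did in all 3, so the size and order of such changes depend on background.

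**Figure D1:**
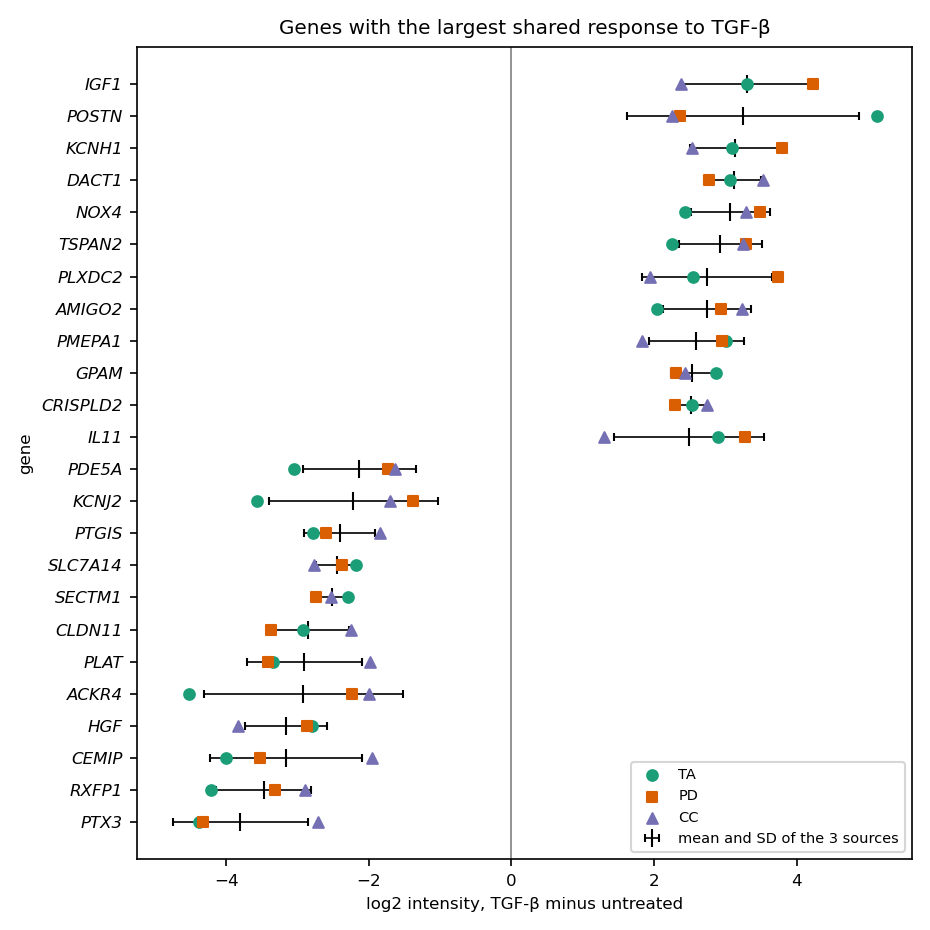
Log2 intensity with TGF-β minus without (horizontal axis) for the 24 genes with the largest shared rise or fall; symbols are the 3 sources, 1 array pair each, and the black mark and bar are their mean and SD (n = 3). The TA symbol of POSTN lies at 5.12, apart from PD at 2.37 and CC at 2.25, and the CC symbol of PTX3 lies at −2.71 against −4.38 for TA and −4.32 for PD.

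All 800 of these genes moved the same way in all sources, which the test itself demands, since its error is the spread between them. Of the 800, 141 rose and 123 fell by at least 2-fold on average, with 18 rising and 15 falling by at least 4-fold. Of all genes tested, 46.8% moved the same way in the 3 sources, where chance gives 25%. At an unadjusted p under 0.05 there were 2515 genes. The count at the adjusted threshold depended on which sources were used and on the block. Without CC, 146 genes passed and POSTN, NOX4, TSPAN2, PLXDC2, AMIGO2, ACKR4, KCNJ2 and PDE5A did not. Of 76 called genes named by the TGF-β and list rules, 32 passed without CC. Without the block 57 genes passed. At an unadjusted p under 0.05, however, limma gave 2340 genes without CC, against 2170 without TA and 1916 without PD. That count was therefore not lowest without CC. A plain paired statistic, which does not share the spread between genes, called 0 genes (1587 at an unadjusted p under 0.05).

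Among gene groups, the list of early TGF-β targets moved most. Of its 17 tested members 11 rose and 0 fell (15 and 0 adjusted over the list alone), led by DACT1, TSPAN2, PMEPA1 and IL11, with a median log2 change of 1.18. Feedback genes were among them: SKIL rose by 1.61 ± 0.20 and SMAD7 by 1.24 ± 0.16. The list's adjusted p was 4.7e-13 by limma's camera, 0.00422 by fry and 0.317 by camera with an estimated correlation. That correlation was −0.03, below the preset 0.01, so the higher p does not come from correlation between its genes. Genes for ligands, receptors and latency proteins went both ways, with 3 of 20 up and 5 down (6 and 7 adjusted over the list alone). This list did not pass by camera (adjusted p = 0.419) but was lower by fry (adjusted p = 0.0102). The activin subunit gene INHBA rose by 1.83 ± 0.63 and the receptor TGFBR1 by 0.95 ± 0.52, while the co-receptor TGFBR3 (−1.65 ± 0.23) and the signal transducer SMAD3 (−1.39 ± 0.09) fell. GREM1, a BMP antagonist, changed by −1.13 ± 0.94 and did not pass (adjusted p = 0.0889).

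Several collagen genes and genes of enzymes that modify collagen rose. Of 19 collagens 8 rose and 0 fell (9 and 4 adjusted over the list alone), with COL4A1 at 1.49 ± 0.48, COL11A1 at 1.12 ± 0.17, COL1A1 at 1.11 ± 0.23 and COL3A1 at 1.11 ± 0.11 (camera adjusted p = 0.00373; adjusted p = 0.594 with an estimated correlation). Of 20 genes of collagen processing and cross-linking 5 rose and 0 fell (6 and 2 adjusted over the list alone). These were the prolyl hydroxylase subunits P4HA3 (1.43 ± 0.06) and P4HA2 (0.93 ± 0.13), the lysyl hydroxylase PLOD2 (1.29 ± 0.61), P3H1 (0.58 ± 0.14) and BMP1 (0.48 ± 0.11). That list had a camera adjusted p of 0.00212, an adjusted p of 0.582 with an estimated correlation and a fry adjusted p of 0.00152. Matrix glycoproteins and proteoglycans had 4 of 15 up and 1 down (8 and 3 adjusted over the list alone): POSTN, the proteoglycan VCAN (1.19 ± 0.51), CCN1 (1.06 ± 0.47) and BGN (0.72 ± 0.36) rose and CCN3 fell (−1.23 ± 0.40). Its camera adjusted p was 0.0315, but 0.0881 in the upper 40% of genes by intensity and 0.582 with an estimated correlation. Of 14 elastic fibre genes, elastin ELN (1.49 ± 0.61) and MFAP2 (1.01 ± 0.13) rose and FBN2 fell (−0.93 ± 0.28), 2 up and 1 down (4 and 2 adjusted over the list alone; camera adjusted p = 0.634), and MFAP4 stood at 0.77 ± 0.47 (adjusted p = 0.0566).

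Matrix protease genes went both ways: of 19 proteases and inhibitors 1 rose, 5 fell and 13 did not pass (5 up and 7 down adjusted over the list alone). The camera adjusted p was 0.398, but 0.0316 without TA and 0.0366 without PD, both downward. Besides PLAT, the aggrecanase family gene ADAMTS1 fell (−1.84 ± 0.83), as did PLAU, urokinase (−1.23 ± 0.46), while MMP1, interstitial collagenase, changed by −0.998 ± 1.03 and did not pass (adjusted p = 0.148). The median of this list was 0.002 although its mean was −0.35. Contractile genes rose in part. Of 19 myofibroblast genes 8 rose and 1 fell (8 and 2 adjusted over the list alone), among them tropomyosin TPM1 (1.82 ± 0.20), N-cadherin CDH2 (1.77 ± 0.51), smooth muscle actin ACTA2 (1.43 ± 0.44) and the collagen-binding integrin ITGA11 (1.26 ± 0.53). The member that fell was SYNPO2, an actin-binding protein gene (−0.85 ± 0.45). The list's camera adjusted p was 0.00212, and its adjusted p with an estimated correlation was 0.651; without the CC pair it was 0.0620 and past the threshold no longer.

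Genes of amino acid supply and of the endoplasmic reticulum stress response rose as a list by camera (adjusted p = 5.4e-08), but not with an estimated correlation (adjusted p = 0.582) or by fry (adjusted p = 0.0990). That estimated correlation was 0.49, the highest among the 22 tested lists, against the preset 0.01. The camera p at the preset therefore counts genes that vary together as nearly independent. Of 20 members 8 rose and 0 fell (13 and 0 adjusted over the list alone). CHAC1 (1.54 ± 0.42), the amino acid transporter SLC7A5 (1.36 ± 0.31), asparagine synthetase ASNS (1.36 ± 0.84) and the proline synthesis enzyme PYCR1 (0.81 ± 0.27) rose. PSAT1, of serine synthesis, stood at 1.20 ± 0.97 and did not pass (adjusted p = 0.0826). Redox genes had a median change of −0.36, with 2 of 17 up and 3 down (2 and 7 adjusted over the list alone). NOX4 and GPX7 rose, while manganese superoxide dismutase SOD2 (−1.16 ± 0.61), thioredoxin reductase TXNRD1 (−1.08 ± 0.63) and the quinone reductase NQO1 (−0.80 ± 0.19) fell. Glutathione peroxidase GPX3 stood at −0.82 ± 0.59 (adjusted p = 0.0731). The camera adjusted p was 0.00790, and the adjusted p with an estimated correlation was 0.582. The stem cell factor list was also lower by camera (adjusted p = 0.0110; adjusted p = 0.582 with an estimated correlation), but of its 7 tested members only LY6E, a membrane protein gene, fell (−0.64 ± 0.26), 0 rose and 1 fell (0 and 4 adjusted over the list alone); KLF4 stood at −0.51 ± 0.26, NT5E at −0.45 ± 0.33 and NES at −0.40 ± 0.28. This list did not pass without the CC pair either (adjusted p = 0.146), nor in the upper 40% of genes by intensity (adjusted p = 0.0881).

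**Figure D2:**
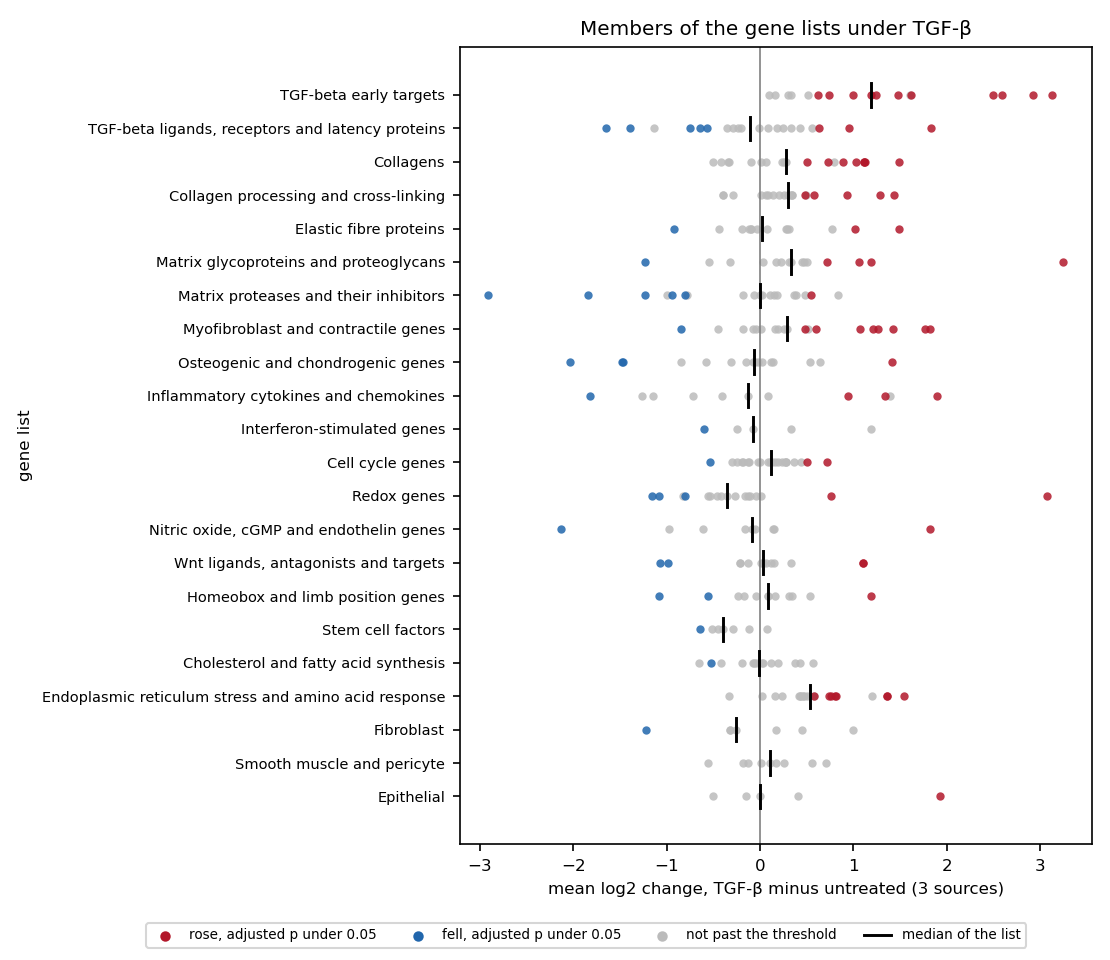
Mean log2 change with TGF-β over the 3 sources (horizontal axis) of each tested member of the 22 lists with at least 5 members; red members rose and blue members fell past the limma threshold, grey members did not pass, and the black line is the list's median. The early TGF-β targets have a median of 1.18 and no blue member, and the matrix proteases reach −2.91 at PLAT.

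The remaining lists had no call by camera with all sources and the filter on dim genes. Of 11 inflammatory genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.760): PTGS2, the inducible cyclooxygenase, rose by 1.89 ± 0.22, IL6 by 1.33 ± 0.41 and LIF by 0.94 ± 0.15, the adhesion gene VCAM1 fell (−1.83 ± 0.46), and TNFAIP6 stood at 1.39 ± 0.98 (adjusted p = 0.0573). Of 16 osteogenic and chondrogenic genes 1 rose and 3 fell (3 and 5 adjusted over the list alone). The camera adjusted p was 0.137, but 0.0316 without TA and 0.0174 without PD, both downward. Osteoprotegerin TNFRSF11B (−2.03 ± 0.60), BMP4 (−1.48 ± 0.16) and aggrecan ACAN (−1.47 ± 0.37) fell and BMP6 rose (1.41 ± 0.87). In the nitric oxide, cGMP and endothelin list 1 of 9 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.5), endothelin EDN1 (1.82 ± 0.47) and PDE5A; EDNRB stood at −0.98 ± 2.01 and GUCY1B1 at −0.61 ± 0.59. Of 13 Wnt genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.844): WNT5A (1.11 ± 0.71) and FZD8 (1.10 ± 0.64) rose, and WNT2B (−1.07 ± 0.34) and the Wnt antagonist SFRP1 (−0.99 ± 0.42) fell. Of 12 homeobox and limb position genes HOXD10 rose (1.19 ± 0.12) and TBX18 (−1.08 ± 0.68) and TBX2 (−0.56 ± 0.17) fell, 1 up and 2 down (3 and 2 adjusted over the list alone; camera adjusted p = 0.776), and HOXD11 stood at 0.53 ± 0.43. Of 22 cell cycle genes CCNA2 (0.72 ± 0.38) and CDK1 (0.50 ± 0.14) rose and TYMS fell (−0.54 ± 0.19), 2 up and 1 down (2 and 1 adjusted over the list alone; camera adjusted p = 0.533); none of these 3 passed without TA, without PD or without CC. Of 5 interferon-stimulated genes IFI6 fell (−0.60 ± 0.24), 0 up and 1 down (1 and 1 adjusted over the list alone; camera adjusted p = 0.793, but 0.00265 downward with no filter), and IFI44L stood at 1.19 ± 0.83 (adjusted p = 0.0589). Of 14 genes of cholesterol and fatty acid synthesis CYP51A1 fell (−0.52 ± 0.18), 0 up and 1 down (1 and 3 adjusted over the list alone; camera adjusted p = 0.760).

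Of the tested cell type markers 3 passed, S100A4, DSP and PPARG. Of 7 fibroblast markers S100A4 fell (−1.22 ± 0.13), 0 up and 1 down (1 and 2 adjusted over the list alone; camera adjusted p = 0.455), and FAP stood at 1.00 ± 0.73. Of 9 smooth muscle and pericyte markers 0 passed, with MCAM at 0.71 ± 0.66 (0 adjusted over the list alone; camera adjusted p = 0.760). Of 5 epithelial markers desmoplakin DSP rose (1.93 ± 0.21), 1 up and 0 down (1 and 0 adjusted over the list alone). The epithelial list did not pass by camera (adjusted p = 0.573) but was higher by fry (adjusted p = 0.0269). Of 4 adipocyte markers PPARG, the regulator of fat cell differentiation, fell (−1.75 ± 0.47), 0 up and 1 down (0 and 1 adjusted over the list alone). With no filter all 10 were tested, and the adipocyte list was lower by camera at the preset correlation (adjusted p = 0.00265). An estimated correlation was not run without the filter, and the members added lie under its floor. The endothelial list had 1 tested member, CLDN5 (−0.21 ± 0.28), the leukocyte list 2, CD68 (−0.51 ± 0.68) and TYROBP (−0.14 ± 0.26), the Schwann and neural list 1, NGFR (−0.25 ± 0.22), and the skeletal muscle progenitor list 2, MYF5 (−0.27 ± 0.44) and MYOG (−0.07 ± 0.18); 0 of them passed.

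Each source was then read on its own, from 1 pair of arrays and without a test. TGF-β moved 156 genes up and 168 down by at least 2-fold in TA, 185 up and 203 down in PD, and 291 up and 158 down in CC. The split in CC depended on scaling, with 209 up and 168 down after quantile normalisation and 353 up and 136 down after median centring. In all 3 sources 78 genes were up and 60 down, of 717 genes that moved 2-fold in any. Responses correlated across genes at r = 0.694 (rho 0.546) between TA and PD, 0.560 (rho 0.403) between TA and CC, and 0.603 (rho 0.457) between PD and CC. The collagen list had a median response of 0.50 in TA and 0.56 in PD (percentile 100 of the random lists in both) and of 0.04 in CC (percentile 40.9). The CC value was −0.10 after quantile normalisation and 0.12 after median centring. The 8 called collagens rose in CC too, as a call demands, for example COL4A1 by 1.54 and COL1A1 by 1.37. Members below the CC median, such as COL14A1 (−0.93) and COL6A2 (−0.47), had not passed. The amino acid and stress list had medians of 0.48, 0.33 and 0.90 in TA, PD and CC, and the myofibroblast list 0.06, 0.25 and 0.51. Median centring would shift the median response in CC from 0.05 to 0.12.

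Single genes stood out by source. In TA, POSTN had a log2 response of 5.12 and SLC7A8, an amino acid transporter, of 2.59 (−0.03 in PD and −0.38 in CC), and the chemokine gene CCL2 had a response of −3.42, against 0.25 in PD and −0.27 in CC. ADH1A was at 0.16 in TA against −1.78 in PD and −2.43 in CC, and ACKR4 at −4.52 in TA. In PD, the water channel AQP1 had a response of 3.09 (−0.23 in TA, 1.06 in CC), CH25H of 2.62, the alarmin IL33 of 1.59 and the chemokine CXCL12 of −3.08, against −0.13 in TA and −0.60 in CC. MAMDC2 and TNFAIP6, at −0.26 and 0.26 in PD, stood at 1.60 and 2.01 in TA. The Wnt antagonist SFRP4 was lower with TGF-β in TA (−1.81) and higher in PD (1.41). In CC, cardiac actin ACTC1 had a response of 2.82, CALHM5 of 1.99 and LRRC17 of 1.82 (−1.09 in PD), the endothelin receptor EDNRB of −3.26 against 0.52 in TA and −0.21 in PD, the chemokine CXCL1 of −1.76 and PTPRN of −0.40. CEMIP and IL11 had their smallest responses in CC, at −1.96 and 1.30. Some of these genes lay under the filter floor of 6.77 in both states of a source. In TA these included EDNRB (4.62 and 5.14), AQP1 (6.46 and 6.23) and ADH1A (6.60 and 6.76), and in CC PTPRN (6.35 and 5.96). A small response on such arrays cannot be told from background.

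PD cells were next set against TA cells, the diseased against the normal sheath. At least 2-fold in both states, 78 genes were higher and 34 lower in PD. Under the naming rule, those higher in PD included CHI3L1, a secreted glycoprotein (log2 difference 6.22 without and 4.70 with TGF-β), enteric smooth muscle actin ACTG2 (4.50 and 5.15), the myogenic factor MYF5 (5.35 and 4.48), the position gene HOXD10 (4.03 and 3.99), EDNRB (4.63 and 3.90), the transcriptional cofactor ZFPM2 (3.63 and 4.04), the hindlimb factor TBX4 (3.54 and 2.99) and CCKAR (2.66 and 2.64). In TA all 8 lay under the filter floor of 6.77 in at least 1 state, so these are differences from background and their order depends on it. The same holds for other differences against an intensity under this floor. The lowest were DSP (−2.13 and −2.38), LCE2C (−2.78 and −2.10), DOK5 (−1.86 and −2.33), LCE2A (−2.30 and −1.82), the smooth muscle coactivator MYOCD (−2.29 and −1.78), ADGRL2 (−2.34 and −1.69), DNER (−1.66 and −3.03) and ABI3BP (−1.62 and −3.23). LCE2A and LCE2C are close paralogs, so their probe sets may not tell them apart. Among the 22 lists with at least 5 tested members, the inflammatory list had the highest median, 0.89 without and 0.67 with TGF-β (percentile 100), with VCAM1 at 1.84 and 1.14 and IL6 at 1.59 and 1.13. It was higher in CC than TA as well (0.51 and 0.69, percentile 99.9) and stood at 0.05 and 0.21 for PD against CC (percentile 67.7). Of its 11 tested members 2 were at least 2-fold higher in PD than TA in both states and 0 lower. CCL2 was lower in PD without TGF-β (log2 intensity 11.22 against 12.60 in TA) and higher with it (11.47 against 9.18). CXCL12 was higher in PD without TGF-β (10.50 against 8.90) and lower with it (7.41 against 8.77). Matrix and bone genes higher in PD included COL14A1 (2.34 and 2.36), COL3A1 (1.55 and 1.65), BMP4 (2.12 and 2.29), MMP3 (2.27 and 2.75), MGP (2.35 and 3.49) and TGFB2 (1.59 and 1.46), although the median was 0.06 and 0.27 for the collagen list (percentile 73.8) and 0.08 and 0.06 for the osteogenic list (percentile 69.3). CC cells were above TA as well for COL14A1 (1.51 and 0.88), COL3A1 (1.02 and 1.23), MGP (3.65 and 4.04) and TGFB2 (0.79 and 0.32), so an excess over TA is not particular to PD for these genes. The lists of matrix glycoproteins (0.29 and 0.11), collagen processing (0.15 and 0.23), elastic fibres (0.14 and 0.12), TGF-β ligands, receptors and latency proteins (0.26 and 0.24) and proteases (0.39 and 0.01) had small positive medians, at percentiles 99.3 to 100. The homeobox and limb position list stood at 0.31 and 0.29 (percentile 100). The fibroblast marker list was also higher, at 0.81 and 0.22 (percentile 100), with DCN at 1.09 and 1.20, and so was the smooth muscle and pericyte list, at 0.13 and 0.36 (percentile 99.7). The lowest percentiles among the 22 lists were those of the amino acid and stress list (−0.09 and −0.19, percentile 1.1), the myofibroblast list (−0.12 and 0.11, percentile 4.0) and the Wnt list (−0.12 and 0.04, percentile 7.1).

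**Figure D3:**
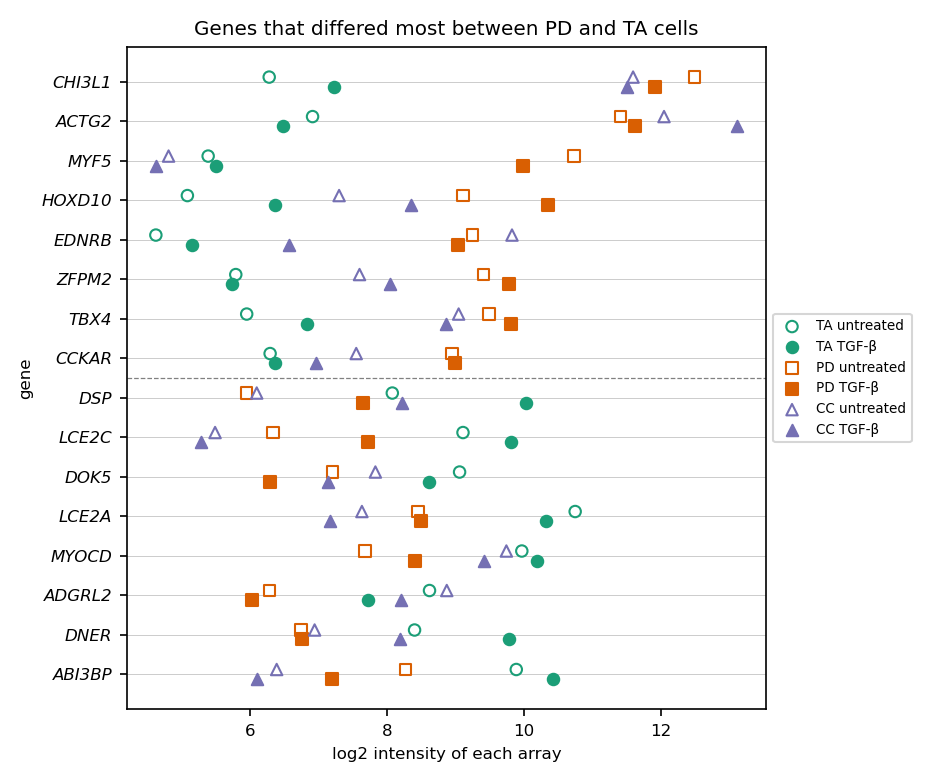
Log2 intensity (horizontal axis) of the 8 genes with the largest excess in PD over TA (above the dashed line) and the 8 with the largest deficit, 1 symbol per array, open without and filled with TGF-β. MYF5 lies at 10.73 and 9.98 in PD and between 4.62 and 5.50 on the other arrays, whereas CHI3L1 (11.51 to 12.49) and ACTG2 (11.41 to 13.12) are bright in both PD and CC.

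Against CC, 210 genes were higher and 135 lower in PD. MYF5 (5.93 and 5.36), the bicarbonate transporter SLC4A4 (3.52 and 2.81), retinol-binding protein RBP4 (2.81 and 3.03), the retinaldehyde dehydrogenase ALDH1A1 (2.49 and 3.80), FGF11 (2.29 and 2.84), PSG4 (2.60 and 2.26), LMO3 (2.13 and 2.37) and the kinin receptor BDKRB1 (2.08 and 2.41) were the highest in PD. ADGRL2 (−2.59 and −2.17), the histone genes H4C3 (−2.14 and −2.47), H2BC3 (−1.92 and −2.59) and H4C6 (−1.83 and −2.07), GPM6B (−2.56 and −1.97), SFRP4 (−3.33 and −1.94), FBN2 (−2.05 and −1.69) and the spindle checkpoint gene MAD2L1 (−1.78 and −1.68) were the lowest. The contractile list was lower in PD than in CC, with a list median of −0.64 and −0.71 (percentile 0) and TAGLN at −2.08 and −1.40, ACTA2 at −1.72 and −1.02 and CNN1 at −1.34 and −1.40. Of the 19 members 4 were at least 2-fold lower in both states and 1, CDH2, was higher (1.73 and 1.27). Cell cycle genes were lower too, at −0.54 and −0.47 (percentile 0). COL1A1 was higher in PD (1.77 and 1.37), and the homeobox list stood at 0.41 and 0.78 (percentile 100).

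CC against TA gave 206 genes higher and 203 lower in CC. ACTG2 (5.14 and 6.64), CHI3L1 (5.32 and 4.29), the calcification inhibitor MGP (3.65 and 4.04), the protease inhibitor SLPI (3.38 and 2.65), EYA1 (3.38 and 2.55), H4C3 (2.49 and 2.54), H1-1 (2.38 and 3.41) and CYP1B1 (2.37 and 3.50) were the highest. Keratin KRT34 (−5.01 and −3.68), LCE2C (−3.63 and −4.54), ABI3BP (−3.51 and −4.33), LCE2A (−3.12 and −3.15), the somatostatin receptor SSTR1 (−3.31 and −2.57), ITGA6 (−2.39 and −2.48), ALDH1A1 (−2.29 and −3.03) and PSG4 (−2.56 and −2.27) were the lowest. The myofibroblast list was higher in CC, at 0.45 and 0.82, with LMOD1 at 1.80 and 2.91 and ACTA2 at 2.02 and 2.13, and so was the cell cycle list, at 0.78 and 0.60 (percentile 100 for both). The CC arrays had lower medians than the others over all clusters. Over the tested genes they did not, with log2 medians of 8.21 and 8.32 in CC against 8.21 to 8.27 on the other arrays. Clusters without any gene symbol stood apart in CC more often than elsewhere (2.71% against 0.0553% in TA and 0.138% in PD), which bears on each difference that involves CC. Median centring, which aligned the medians over all clusters, moved the median of the tested genes from 0.01 to 0.21 for CC against TA, and to −0.14 for PD against CC. It changed the splits to 393 higher and 116 lower in CC than TA and to 127 higher and 217 lower in PD than CC. These shifts follow from that setting and do not show that the deposited differences are mis-scaled.

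Genes that set 1 source apart from both others in both states were fewest in PD. There were 22 higher and 6 lower in PD, 17 higher and 35 lower in TA, and 82 higher and 105 lower in CC (152 and 53 after median centring). MYF5 was at least 22.3-fold, LMO3 4.32-fold, HOXD10 3.51-fold, SBSPON 3.40-fold, RBP4 3.37-fold and ZFPM2 3.33-fold higher in PD than on any array of another source in the same state. The log2 gaps nearest to 0 for genes lower in PD were −1.69 for ADGRL2, −1.50 for STEAP1B, −1.28 for GPM6B, −1.02 for the carboxypeptidase CPA4 and −1.01 for MYOCD. TA stood apart by high LCE2C (smallest log2 gap 2.10), LCE2A (1.82), DSP (1.81), ABI3BP (1.62), DNER (1.46) and ADGRL4 (1.36), and by low ACTG2 (−4.50), CHI3L1 (−4.29), MGP (−2.35), H1-1 (−2.31), SLPI (−2.06) and TBX4 (−2.03). CC stood apart by the histone genes H4C3 (2.14), H2BC3 (1.92), H4C6 (1.83) and H4C13 (1.55), whose near-identical copies may share probes, by MAD2L1 (1.68) and RARRES2 (1.61), and by low ALDH1A1 (−2.29), PSG4 (−2.26), BDKRB1 (−2.08), SLC4A4 (−2.01), LDOC1 (−1.90) and SSTR1 (−1.81). None of these differences between sources has a replicate check.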

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

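The tests of the intensity distribution, of muscle progenitor cells, of the MYF5 probe set, of the CC pair alone and of chaperone genes, and the other splits for the gene count, were chosen after the result was seen; the test on clusters without a gene symbol and the splits for the list count were not.

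Among the genes named for the response of a single source, the only ones searched, the response to TGF-β of 3 went up in 1 source and down in another by at least 1.5-fold each, a difference between single array pairs that was not tested. SFRP4 was at −1.81 in TA and 1.41 in PD, a difference of −3.22. IL33 was at 1.59 in PD and −0.74 in CC, a difference of 2.34. LRRC17 was at −1.09 in PD and 1.82 in CC, a difference of −2.91. Among clusters that the comparisons did not use, 5 of the 978 tested clusters with several gene symbols passed the threshold for TGF-β (3 rose and 2 fell), and 0 of 3619 without a symbol did, each kind in a limma fit of its own.

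The TGF-β gene count of 800 compares with 10 ways to split the 6 arrays into 3 and 3, which are too few for a share under 0.05. Only 1 split, the real one, gave as many genes, and the highest of the others gave 0. The 3 other splits that part every source pair also gave 0, with 63 to 173 genes at an unadjusted p under 0.05 against 2515. For the list count of 8, again 1 split gave as many, but the highest of the others gave 7. The 4 splits with 7 lists part only the PD pair or only the TA pair, so that pair's own TGF-β response is what the fit reads, and the 2 that part only the CC pair gave 1 list; the 3 others that part every pair gave 2 or 3 lists.

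CC stood apart by 187 genes, against 28 for PD and 52 for TA. A different intensity distribution of the CC arrays is argued against as the whole cause, since 173 genes remained by count after quantile normalisation, against at most 52 for the other sources. Handling of the CC arrays that shifted probe sets alike stays open: 2.71% of clusters without a gene symbol (98 of 3619, exact binomial 95% interval 2.20 to 3.29%, over clusters) stood apart in CC, against 1.67% of gene clusters matched on intensity. In TA and PD these unnamed clusters stood apart at 0.0553% and 0.138%, below the 0.408% and 0.211% of matched gene clusters. The erectile tissue, its donor and its culture are confounded with these arrays and stay open as well, untested.

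MYF5 was at log2 10.73 and 9.98 in PD cells and near background, 4.62 to 5.50, on the other arrays. Skeletal muscle progenitor cells in the culture cannot be told apart from this, because of 7 other muscle genes (MYF6, MYOD1, MYOG, PAX7, PAX3, CHRNA1 and DES) 5 lie under the filter floor on average; their median log2 difference was 0.16 (SD over genes 0.61), and 0 of them were 2-fold higher in PD than in both other sources in both states. The nearest was CHRNA1, a muscle acetylcholine receptor subunit, higher in PD in all 4 comparisons (log2 differences 0.74 to 2.02). Whether the probe set reads another transcript cannot be told apart from MYF5 itself, because the array has 1 MYF5 probe set. A property of these PD cells or of their donor stays open, as 1 array per source and state gives no test of disease.

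The amino acid and stress list rose with TGF-β by camera at the preset correlation (adjusted p = 5.4e-08), but not with an estimated correlation (adjusted p = 0.582) or by fry (adjusted p = 0.0990), and had its highest median in CC. Without the CC pair the list's adjusted p by limma's camera at the preset correlation was 1.3e-06, and its median over TA and PD was 0.41. The estimated correlation between its genes was 0.49 with all sources, so this p cannot decide whether the CC pair alone carried the call. The medians of 0.48 in TA and 0.33 in PD show only that the rise was not confined to CC. A chaperone response rather than amino acid genes was neither excluded nor borne out: the 7 chaperone members had a median change of 0.41, against 0.73 for the 13 other members. A response of the cells to TGF-β stays open, as a hypothesis.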

How the results depend on the processing

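All settings were listed before the data were examined; the counts apart in TA and CC use those listed for PD. None of the 76 called genes named by the TGF-β and list rules reversed in any of them. Other named genes were not re-checked. The TGF-β count of 800 lay between 648 and 997 under another or no filter, cluster means, both rescalings, a trended and robust prior and an added 1.5-fold threshold. With no replicate block it was 57, all among the 800. Leaving out 1 source gave 146 to 914, the lowest without CC (139 shared with the 800). At an unadjusted p under 0.05 the limma count was not lowest without CC. Each of these fits rests on 4 arrays, and why the adjusted count fell most without CC was not tested. The plain paired statistic gave 0, with a smallest adjusted p of 0.0567; it does not share the spread. Of 24 leading genes, 13 passed with no block and 16 without CC. The list count of 8 was 6 to 10 when a source was left out and under the other settings. With an estimated correlation, up to 0.49 among the 8 lists and tested on 2 degrees of freedom, it was 0. By fry it was 4. Of these 4, early TGF-β targets and collagen processing are among the 8, and the ligand and receptor list and the epithelial list are not. Fry tests whether a list's genes move on balance, not against other genes, and found 20 lists with change in either direction. The number of arrays, and their signal over background at dim probe sets, limit all of this.

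Counts of single-pair results followed the fold threshold. Responses at 1.5-fold and 3-fold were 865 and 111 genes in TA, 1045 and 115 in PD, and 1788 and 119 in CC. Differences were 333 and 43 for PD against TA, 1458 and 53 for PD against CC, and 1563 and 83 for CC against TA. Genes apart were 108 and 8 in PD, 153 and 17 in TA, and 914 and 24 in CC. On untreated arrays only and TGF-β arrays only, differences were 232 and 251 (PD against TA), 626 and 819 (PD against CC) and 656 and 979 (CC against TA), and genes apart were 67 and 77 in PD, 112 and 115 in TA, and 317 and 493 in CC. The upper 40% of genes by intensity gave 70 for PD against TA and 12 apart in PD, and no filter gave 48 apart in PD, as fewer or more genes were tested. Correlations of responses fell to 0.605 (TA and PD), 0.451 (TA and CC) and 0.499 (PD and CC) with no filter. Among genes changed 1.5-fold in either source they were 0.773, 0.683 and 0.716, and in the upper 40% the PD and CC value was 0.675; the cause was not tested. All of these come from single arrays and no test.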

Other observations

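The test of the hypothesis in this part was chosen after the result was seen.

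Several genes that set a source apart also responded to TGF-β in all sources, by limma with the source as a block. Of those high in PD, HOXD10 rose (1.19, adjusted p = 0.00283), while LMO3 (−1.12, adjusted p = 0.00538) and SBSPON (−1.33, adjusted p = 0.00328) fell. Of those low in PD, CPA4 (−1.90, adjusted p = 0.00664), GPM6B (−1.47, adjusted p = 0.00879) and STEAP1B (−0.80, adjusted p = 0.0125) fell. DSP and the adhesion receptor gene ADGRL4, high in TA, rose (1.93 and 0.93, adjusted p = 0.00149 and 0.00535), and BDKRB1, low in CC, fell (−0.81, adjusted p = 0.0152). All moved the same way in 3 of 3 sources, which the test demands of a called gene.

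TGF-β induces plaque resembling the disease in animals, according to the series' design text, so a hypothesis was that TGF-β moves cells of another source towards the PD pattern. It was tested in CC, which shares no array with the comparison of PD and TA. The 149 genes at least 2-fold higher in untreated PD than TA cells had a median log2 response of −0.27 in CC, at percentile 0 of the random lists, and the 83 lower genes had −0.01, at percentile 11.1. Across all genes the PD difference and the CC response correlated at r = −0.0395 (rho 0.0676). Which way CC moved relative to PD cannot be told apart by this test, because 28 of the 149 genes and 25 of the 83 were already at or past the PD level in untreated CC cells. TA could not be used because its untreated array enters both sides.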
